A study of Triticum urartu with 25 samples.

How the data were processed

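The data are 18 RNA-seq libraries in 1 table and 6 peak lists from 4 ChIP-seq and 2 DNase-seq libraries of Triticum urartu G1812 seedlings grown at 22 °C. The series also has 1 bisulfite library, which is not analysed here. Groups and replicate numbers were taken from the sample titles and treatment labels, which also give the treatments. The labels give poly(A) RNA as the molecule of control replicates 1 and 2 and both ABA libraries and total RNA for the other 14, while a protocol text shared by all samples does not tell the types apart. The ABA-treated ChIP library names ABA in its title, and its treatment was read from the series-wide protocol.

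The authors deposited gene expression as FPKM, fragments per kilobase of gene model and library depth, for 41492 genes. The submitters' processing notes name Trim Galore, Trimmomatic, BWA, HISAT2, Bismark, featureCounts and Subread among their tools, with no role or version. The genome build, the annotation and the strandedness of counting are not given in the sources used here, so reads shared by near-identical or overlapping genes may sit in either gene. For 88.3% of the 16706 genes above 0 in at least 6 libraries and under 20 FPKM in all, FPKM values proved to be whole multiples of a step set by library and gene length. From these steps the library totals were recovered. For 29076 genes, 99.6% of those above 0 in any library, reads followed from the shortest gene length that made them whole. The tolerance was 0.02 reads and the upper limit 25000 reads. For genes above 0 in few libraries too short a length can also give whole reads, so their recovered reads may be too low. The totals were 10.5 to 24.1 M reads per library. Reads of the most abundant genes, such as TuG1812G0400002666.01, were not recovered, so no lower bound on its fold was computed.

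Peaks were called with MACS 2.2.6, and for DNase replicate 1 with MACS 2.1.4, per the file headers. Each call used 1 alignment file, no input control, a q cutoff of 0.05, no fragment model, no local background, an extension of 200 bp and an effective genome size of 4821609433. The names of the alignments in the headers say that they were filtered at quality 20, with duplicates and multiple mappers removed. Both DNase alignment names also say that they are merged. What was merged, whether the 2 share reads and whether they are biological replicates is not stated. Per the file headers the lists hold a pileup signal at the summit, −log10 p-values and q-values, and a fold enrichment over the genome-wide background of the same library. Without an input, regions with more mappable or copied sequence can be called as peaks. The fold and q are the authors' own. They were used to rank peaks within a list and to give summit values, and folds of separate libraries without an input are not on one scale. Peak calls with narrow settings can split broad marks such as H3K27me3.

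Expression was compared with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a mean-variance trend, moderated two-sided tests and Benjamini-Hochberg adjustment within each comparison at 0.05. Genes at 1 FPKM or more in at least 2 libraries were tested, 18308 in all. All 18 libraries entered 1 model, which left 11 residual degrees of freedom, and each stress was compared with all 6 controls. Fold changes on this scale understate the change of low genes. A second model added the RNA type as a term. It has 10 residual degrees of freedom, and its stress effects equal comparisons within the RNA type. The table is in FPKM rather than counts, so no count model was the main test, and limma-voom on the recovered reads was an added alternative. TMM factors were computed unweighted from FPKM values. On simulated data for heat versus control over 16731 genes, the model with 6 controls found 1% of genes changed by 1 and 54% of genes changed by 2 on the log2 scale, with 0 other calls. The model with the RNA type found 38% and 99%, with 10 other calls. The simulation gave all genes the same negative binomial spread, and libraries of 1 RNA type the same means apart from the changes set for heat. Changes were placed only in genes at 5 FPKM or more in the controls of both RNA types. Recovery and false calls in the real libraries were not measured. The peak overlap code was tested on simulated lists of 5000 peaks and misplaced 0.

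The named genes follow a rule fixed before the data were examined: adjusted p under 0.05, a mean of 5 FPKM or more in the higher group, both stress libraries outside the range of all 6 controls, then the largest change. Because no names are paired with the identifiers, the rule allows 2 risen and 2 fallen per stress. Genes that met it numbered 3530 risen and 42 fallen for ABA, 11 and 28 for drought, 257 and 160 for cold, 1202 and 707 for heat, 571 and 203 for wounding, and 0 for salt. The gene lists planned for the same comparisons need names or protein sequences, and none of the identifiers matched the reference gene table, so no list was tested. Comparisons of peaks with genes need gene coordinates of the build the peaks use, and were not made. For the overlap of calls, independent lists share n1 × n2 / N genes, 100 sets of unchanged groups were simulated against the same controls, and controls were split without sharing, into 3 and 3 (20 assignments) or within the total RNA libraries into 2 and 2 (6 assignments).

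Peaks were compared with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and bedtools 2.31.1. Overlap means at least 1 bp. Lists were compared on the 7 chromosomes, which hold 91.9% to 97.1% of the peaks. Chromosome extent was the largest peak end in any list. As background, each list was placed at random within the chromosome 100 times, and moved by 200 to 1000 kb either way 100 times. The strength classes of H3K27me3 peaks were moved in the same way. Peaks after ABA were also placed at random 100 times, keeping those that touched no peak of the library without ABA. Shares carry 95% Wilson intervals, which cover counting error only. Alternatives planned before the data were examined were other pseudocounts, filters, scalings, fits, control subsets, a replicate block, leaving out each library, and stricter peak sets or overlaps. The RNA type term, its combinations, and voom were added after the data were seen; the split was first seen in the correlations and then found to match the labels. The closing section gives their effect.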

Results

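Seedlings of the Triticum urartu accession G1812 were profiled by RNA-seq, histone ChIP-seq and DNase-seq. T. urartu is a wild diploid wheat, and the A genome of bread wheat came from its lineage. The series sets the response to abiotic stress beside the chromatin of the same accession, under a title on transposable elements and the wiring of stress-responsive genes. The 18 RNA libraries fall into 6 control libraries and 2 libraries each of ABA, salt, drought, cold, heat and wounding. Per the labels, stress started in seedlings 7 days old: ABA for 2 weeks at 100 μm as the labels write the unit, 250 mM NaCl for 7 h, drought as 2 weeks unwatered, 4 °C for 5 h, 40 °C for 7 h, and leaves cut with sampling 2.5 h later. The labels give no age for the controls and do not assign them to stresses. The series design counts 5 stresses, while the labels hold 6 treatments. The depth behind the FPKM values, recovered from their steps, was 10.5 to 24.1 M reads per library. Recovered reads on genes, without the most abundant genes, were fewer. They numbered 2.53 to 5.22 M in the total RNA libraries and 11.97 to 14.92 M in the poly(A) libraries. Each library had 11854 to 17064 genes at 1 FPKM or more. Chromatin was covered by 1 library each of H3K27me3, H3K27me3 after ABA, H3K9ac and H3K4me3 and by 2 DNase-seq libraries. These held 28.3 to 37.5 M tags after filtering for ChIP, and 191.0 and 26.8 M for DNase replicates 1 and 2. Nothing in the labels says that replicates came from separate plants or pools, so p-values measure only the spread between these libraries. The table lists gene identifiers that the files do not pair with names. Results are therefore given by count, with at most 2 identifiers per direction and stress.

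The labels give 2 RNA types, and they divide the control group. Control replicates 1 and 2 and both ABA libraries are labelled poly(A) RNA, and the other 14 libraries are labelled total RNA. The libraries separated by this label on the main axis of variation. Pearson correlations across genes on log2(FPKM + 1) were 0.877 to 0.985 within the 4 poly(A) libraries, 0.764 to 0.980 within the 14 total RNA libraries, and 0.664 to 0.797 between them; genes are not independent replicates. That axis, 51.7% of the variance, placed the poly(A) libraries between -157.7 and -124.1 and the others between -0.1 and 78.3. FPKM summed over genes to 573184 to 584814 in poly(A) libraries and to 258137 to 347068 in total RNA libraries. Identifier TuG1812G0200002505.01 stood at 10.5 and 8.21 FPKM in control replicates 1 and 2 and at 1934 to 3695 FPKM in control replicates 3 to 6. Between these control libraries 10910 of 18308 tested genes passed an adjusted p of 0.05 (limma, Benjamini-Hochberg), and 7676 did so after TMM scaling. Of these, 10060 and 4279 were higher in control replicates 1 and 2. The planned comparison with all 6 controls therefore mixes RNA types. Each count of called genes is given in that form and again within the RNA type, where ABA faces control replicates 1 and 2 and every other stress faces control replicates 3 to 6. The second form was chosen after the correlations were seen. Named genes are given against 6 controls, with the log2 change within the RNA type for ABA and where the 2 differ by more than 0.5. The 16 named for other stresses were also called within the RNA type. Scaling also mattered. TMM moved the median log2 change of all genes against 6 controls from 0.75 to -0.01 for ABA and from 0.12 to -0.02 for heat. Within the RNA type it moved the median from 0.37 to 0 for heat, from 0.30 to -0.01 for wounding and from 0.26 to 0.01 for ABA, so rises and falls below are relative to a scale common to all genes of a library. No named result below reversed its sign under TMM or quantile scaling.

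**Figure D1:**
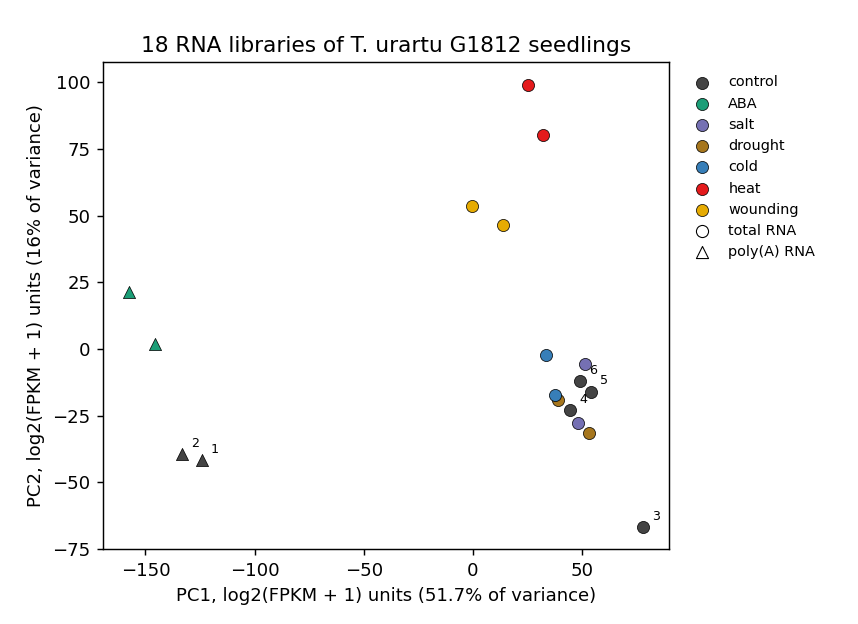
Principal components of log2(FPKM + 1) over 18308 genes, with 1 point per RNA library coloured by group, shaped by RNA type, and control replicates numbered. The poly(A) libraries, control replicates 1 and 2 and ABA, lie at -124.1 or below on PC1 (51.7% of the variance), the other 14 libraries at -0.1 or above, and heat and wounding lie highest on PC2 (16% of the variance).

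Heat for 7 h at 40 °C changed the most genes among the 5 treatments other than ABA. Against 6 controls 2878 genes passed limma's test, 1972 higher and 906 lower. Against control replicates 3 to 6 alone, within the RNA type, 7033 passed, 5665 higher and 1368 lower, and all 2878 were among them in the same direction. The strongest riser, TuG1812G0400002666.01, was listed at 0 in all 6 controls and at 1938 and 3942 FPKM after heat, against 0.74 FPKM or less in every other stressed library. The gene with the next lower number, TuG1812G0400002665.01, went from 0.0869 ± 0.138 FPKM (SD, n = 6) to 583.5 ± 327 FPKM (SD, n = 2), a log2 change of 8.96 ± 0.26 (SE, limma adjusted p = 2.45e-11). It rested on 3968 and 7951 reads after heat against 4 or fewer in each control library. On the falling side TuG1812G0600000962.01 went from 256.0 ± 116 FPKM (SD, n = 6) to 0.374 ± 0.403 FPKM (SD, n = 2), a log2 change of -7.44 ± 0.50 (SE, limma adjusted p = 2.07e-07). It was also lower after drought, cold and wounding, at limma adjusted p = 0.0299, 0.0242 and 0.00691. TuG1812G0300004779.01 went from 409.4 ± 53.9 to 4.00 ± 0.741 FPKM, and was at 86.4 FPKM after wounding and 141.4 FPKM after cold, also below its controls at adjusted p = 0.000521 and 0.0178. A group of 48 genes lay under 1 FPKM in all 6 controls and at 5 FPKM or more in both heat libraries, and 20 showed the reverse. For comparison, pairs among control replicates 3 to 6 gave at most 2 such genes in either direction against the other 4 controls. Pairs of 1 poly(A) and 1 total RNA control say little. Their other 4 controls include the second poly(A) control, which correlated with the first at 0.985. With TMM scaling rises made up 47.7% of 4038 calls in place of 68.5%, and within the RNA type 48.1% of 5308 in place of 80.5%. The count against 6 controls was 925 without heat replicate 1 and 631 without heat replicate 2, and within the RNA type it was 4621 and 3325.

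Wounding of leaves changed 1141 genes against 6 controls after 2.5 h, 909 higher and 232 lower (limma). Total RNA controls alone gave 5128 genes, 4422 higher and 706 lower, again with all 1141 kept in direction. TuG1812G0100004039.01 rose from 0.683 ± 0.628 FPKM (SD, n = 6) to 313.9 ± 37.5 FPKM (SD, n = 2), a log2 change of 7.62 ± 0.42 (SE, limma adjusted p = 3.49e-08). It also rose after heat, to 111.0 and 355.7 FPKM (adjusted p = 5.52e-08). TuG1812G0300003907.01 rose to 460.2 ± 190 FPKM after wounding (log2 change 7.46 ± 0.68, SE) and to 64.9 FPKM after heat, from 2.34 ± 2.83 FPKM in controls. The 2 largest falls were TuG1812G0100004554.01, from 92.9 ± 115 to 2.84 ± 2.28 FPKM, and TuG1812G0100004552.01, from 47.2 ± 41.7 to 3.33 ± 3.94 FPKM. The poly(A) controls raise these control means: the first stood at 232.6 and 249.9 FPKM in control replicates 1 and 2 and at 14 to 23.8 FPKM in the others, and the second at 94.4 and 106.4 FPKM and at 15.1 to 27 FPKM. Their log2 changes were -3.69 and -3.42 against 6 controls and -2.48 and -2.66 within the RNA type (limma adjusted p = 0.000185 and 0.00158). The first missed with voom against 6 controls (adjusted p = 0.0604). Both were also lower after heat, at adjusted p = 0.0166 and 0.00101. Without wounding replicate 1 their adjusted p was 0.464 and 0.405, and without replicate 2 it was 0.134 for the first. In 39 genes both wounded libraries held 5 FPKM or more while all 6 controls held under 1 FPKM. TMM scaling brought the share of rises from 79.7% to 54.9% of 2685 calls, and within the RNA type from 86.2% to 53.7% of 4789. Without wounding replicate 1 the count against 6 controls was 242 and without replicate 2 it was 402, and within the RNA type 2336 genes passed without replicate 1.

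Cold for 5 h at 4 °C changed 569 genes against 6 controls, 338 higher and 231 lower (limma), and 2616 within the RNA type, 1925 higher and 691 lower, with all 569 kept in direction. TuG1812G0700005249.01 rose from 1.43 ± 0.827 FPKM (SD, n = 6) to 226.1 ± 4.79 FPKM (SD, n = 2), a log2 change of 6.63 ± 0.37 (SE, limma adjusted p = 6.55e-08), and its mean stayed under 5 FPKM in the 5 other stresses. Within the RNA type it was also called higher after wounding, at 4.29 FPKM (log2 change 1.47, limma adjusted p = 0.00267). TuG1812G0200005061.01 rose to 191.5 ± 33.1 FPKM from 1.25 ± 0.933 FPKM (log2 change 6.53 ± 0.42, SE). It also passed after heat, drought and wounding, at lower means of 18.7, 10.1 and 6.55 FPKM. Among falls, TuG1812G0500003568.01 went from 263.4 ± 214 to 2.22 ± 2.38 FPKM and TuG1812G0200003610.01 from 130.5 ± 81.4 to 5.34 ± 6.38 FPKM, both also lower after heat (adjusted p = 0.00888 and 0.0393). The first stood at 491.9 and 391.1 FPKM in the poly(A) controls and at 19.7 to 458.7 FPKM in the total RNA controls, and the second at 229.0 and 218.4 FPKM and at 15.5 to 129.3 FPKM. Their log2 changes were -5.70 and -4.49 against 6 controls and -4.90 and -3.91 within the RNA type (limma adjusted p = 0.00396 and 0.0107). The first missed with voom, at adjusted p = 0.11 against 6 controls and 0.0723 within the RNA type. Without cold replicates 1 and 2 in turn their adjusted p was 0.0752 and 0.295, and 0.0516 and 0.499. In 14 genes both cold libraries held 5 FPKM or more with all 6 controls under 1 FPKM. Rises were 73.6% of calls within the RNA type, and 55.4% of 3396 calls with TMM. Without the RNA type term, falls outnumbered rises with a pseudocount of 0.1 (350 and 273) and without control replicate 3 (543 and 357). Against 6 controls 1427 genes passed with TMM. The count was 175 without cold replicate 1, 80 without cold replicate 2 and 900 without control replicate 3, and within the RNA type it was 1732 without cold replicate 1 and 1244 without cold replicate 2.

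Drought, given as 2 weeks without water, gave 44 called genes against 6 controls, 15 higher and 29 lower (limma). Within the RNA type 557 were called, 410 higher and 147 lower, with all 44 kept in direction. The labels give no age for the controls, so drought cannot be told apart from a difference in plant age. TuG1812G0600002471.01 rose from 2.69 ± 3.0 FPKM (SD, n = 6) to 41.1 ± 22.3 FPKM (SD, n = 2), a log2 change of 3.66 ± 0.52 (SE, limma adjusted p = 0.0132). TuG1812G0400000516.01 rose from 0.878 ± 0.790 to 8.42 ± 1.27 FPKM, and further after cold, wounding and heat, to means of 27.6, 56.3 and 58.5 FPKM. TuG1812G0200000674.01 fell from 1569 ± 404 to 131.2 ± 51.4 FPKM, a log2 change of -3.59 ± 0.34 (SE, limma adjusted p = 0.000597), and was also lower in ABA, cold, heat and wounding. TuG1812G0500004423.01 fell from 75.4 ± 91 to 0.260 ± 0.0597 FPKM (limma adjusted p = 0.0488), with controls at 240.5 and 123.8 FPKM in poly(A) RNA and 12.3 to 39.2 FPKM in total RNA. Its log2 change was -5.08 against 6 controls and -4.07 within the RNA type (limma adjusted p = 0.00394), and it missed with voom, at adjusted p = 0.236 and 0.0776. The same gene was also lower after heat against 6 controls (limma adjusted p = 0.00996). Of these 4 only the fall of TuG1812G0200000674.01 was also called without each single library. Without drought replicates 1 and 2 in turn the adjusted p was 0.089 and 0.458 for TuG1812G0600002471.01, 0.645 and 0.458 for TuG1812G0400000516.01 and 0.634 and 0.656 for TuG1812G0500004423.01. TuG1812G0400000516.01 also missed without control replicates 4, 5 and 6 (0.0552, 0.0597 and 0.065), and TuG1812G0500004423.01 without control replicates 2, 4 and 6 (0.06, 0.0967 and 0.0615). Against 6 controls TuG1812G0400000516.01 missed with voom too (adjusted p = 0.0695). In limma it missed with pseudocounts of 0.1 and 5 (0.18 and 0.0579) and with quantile scaling (0.0504). Without either drought replicate 3 genes passed against 6 controls, 245 passed without control replicate 3, 21 without control replicate 4 and 22 without control replicate 6. Within the RNA type, 74 and 63 passed without drought replicates 1 and 2, 302 and 313 without control replicates 6 and 5, and 1523 without control replicate 3, whose closest library was drought replicate 1 (r = 0.950 across genes). With TMM 126 genes passed against 6 controls, and within the RNA type rises made up 49.7% of 678 calls in place of 73.6% of 557.

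Salt, 250 mM NaCl for 7 h, gave no gene past the adjusted threshold in limma, either against 6 controls (440 genes at an unadjusted p under 0.05) or within the RNA type (979 genes). With no change at all, a share of 0.05 of the 18308 tested genes would pass that unadjusted limit. The first count was below this share and the second near it. TMM, quantile scaling and limma-voom on recovered reads also called 0 genes. Salt replicate 1 was closest to control replicate 5 (r = 0.967 across genes) and salt replicate 2 to control replicate 4 (r = 0.963), both above the 0.947 between the salt replicates. Every other stressed library was closest to its own partner.

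ABA for 2 weeks gave 5556 genes against 6 controls, 5490 of them higher and 66 lower (limma). Against control replicates 1 and 2, the poly(A) controls, it gave 2578, 1729 higher and 849 lower. As for drought, the treatment cannot be told apart from a difference in plant age. Of the 5556 genes, 1660 were called in the same direction within the RNA type. TuG1812G0100000464.01 rose from 1.0 ± 1.6 FPKM (SD, n = 6) to 216.8 ± 18.3 FPKM (SD, n = 2), a log2 change of 7.08 ± 0.62 (SE, limma adjusted p = 1.96e-06), and by 5.78 ± 0.45 (SE) within the RNA type. TuG1812G0300000549.01 reached 804.6 and 415.4 FPKM, against 29.2 and 26.4 FPKM in control replicates 1 and 2 and 0 to 1.32 FPKM in control replicates 3 to 6. Its log2 change was 7.18 ± 1.10 (SE) against 6 controls and 4.33 ± 0.35 (SE) within the RNA type (limma adjusted p = 6.59e-07). The 2 largest falls against 6 controls, TuG1812G0200002505.01 and TuG1812S0000304700.01, were not called within the RNA type, where their log2 changes were -0.36 ± 0.37 and -0.48 ± 0.25 (SE, limma adjusted p = 0.548 and 0.223). Without ABA replicates 1 and 2 in turn their adjusted p against 6 controls was 0.298 and 0.16, and 0.284 and 0.159; without any of control replicates 3 to 6 it was 0.0759 to 0.0782 and 0.0682 to 0.0705. With TMM 1816 genes passed, 70.7% of them higher, and within the RNA type 45.3% of 1960 were higher. Against 6 controls the count was 301 without ABA replicate 1, 1566 without ABA replicate 2, 9368 and 9819 without control replicates 1 and 2, and 3607, 3433 and 3680 without control replicates 4, 5 and 6. Within the RNA type it was 710 without ABA replicate 1, and 1266 and 1277 without control replicates 1 and 2.

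**Figure D2:**
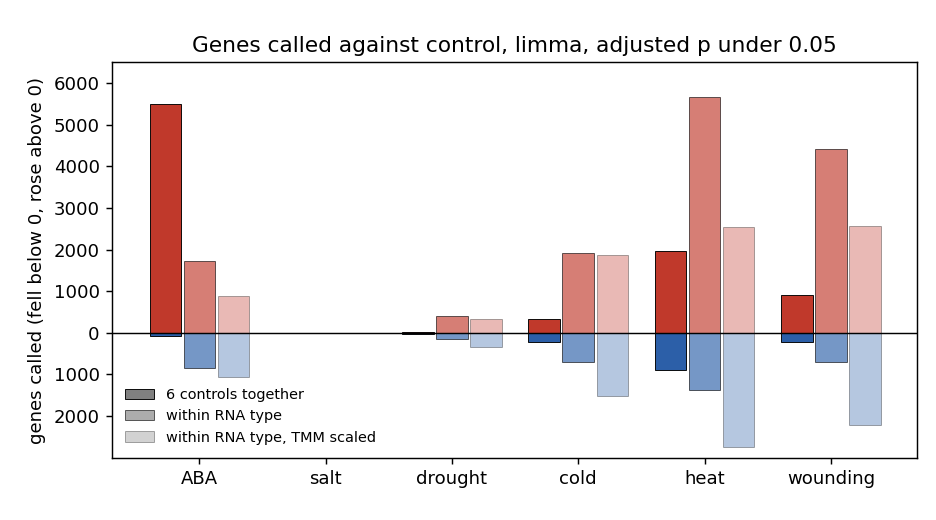
Number of genes past an adjusted p of 0.05 (limma) per stress, rises above 0 and falls below 0, against 6 controls together, within the RNA type, and within the RNA type with TMM scaling. Heat has 2878, 7033 and 5308 calls in that order, and salt has 0 in each.

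**Figure D3:**
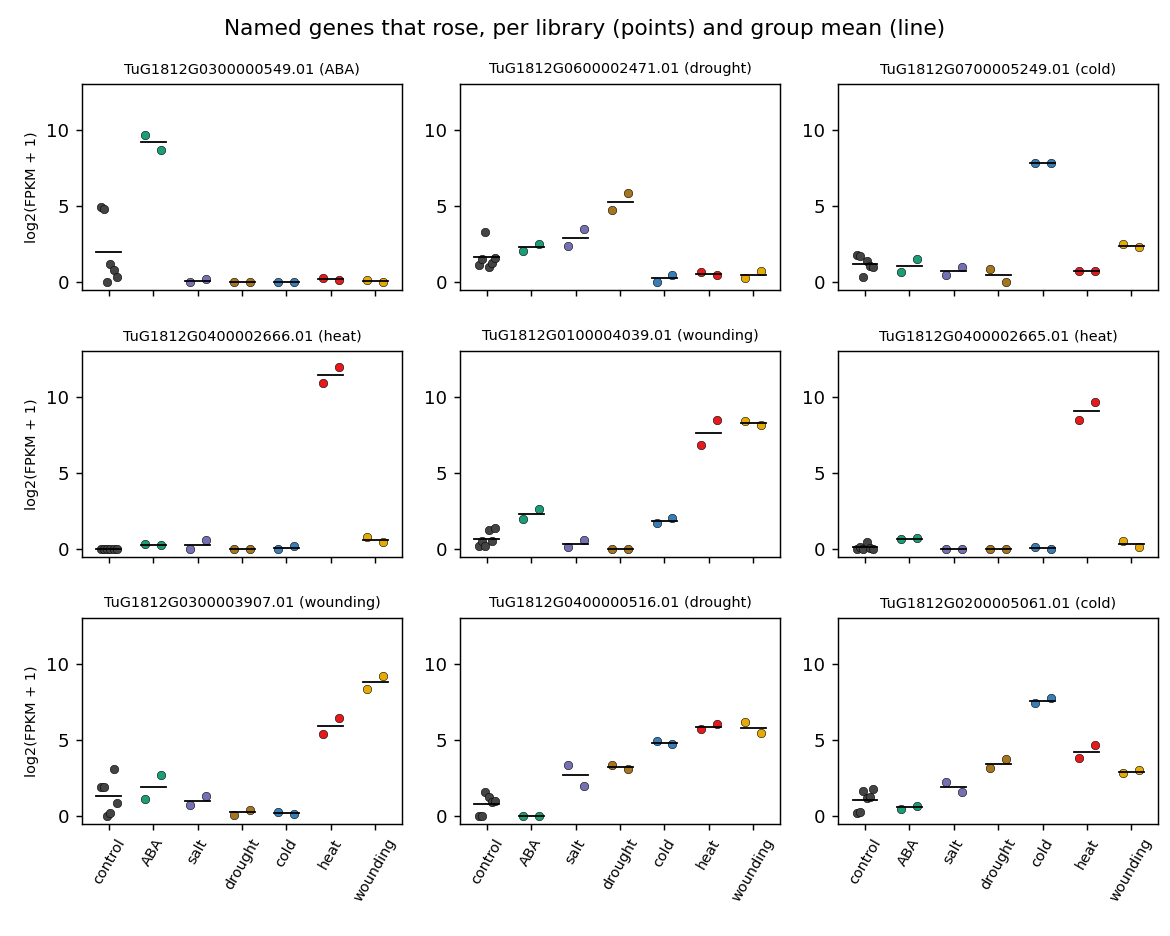
Log2(FPKM + 1) of 9 of the 10 named genes that rose, with 1 point per library and a line at the group mean; the stress that named each gene is in brackets. TuG1812G0400002666.01 is at 1938 and 3942 FPKM after heat only, while TuG1812G0400000516.01 has group means of 27.6 to 58.5 FPKM after cold, wounding and heat.

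Heat and wounding changed many genes alike. Against 6 controls 570 genes were called in both in the same direction, 416 higher and 154 lower, where independent lists of those sizes share 97.9 and 11.5, and 10 were called in opposite directions. When the controls were split so that the stresses shared none, the mean over splits was 575.8 genes. These splits of all 6 controls ignored the RNA type, so the mix of RNA types on each side varied between splits. They therefore cannot say how much of the 570 comes through shared controls. The values for independent lists in this paragraph belong to the lists without split controls. Shared genes numbered 2966 within the RNA type, against 1368.3 rises and 52.8 falls for independent lists and a mean of 2236.2 with split controls. With TMM scaling within the RNA type 2383 were shared, where independent lists share 692.2. The log2 changes of heat and wounding had a covariance across genes of 0.395 within the RNA type, while unchanged groups simulated against the same controls gave 0.030. Cold shared 120 genes with wounding against 6 controls, where independent lists share 16.8 rises and 2.9 falls, and 127 with heat, where they share 36.4 and 11.4. The numbers were 1291 and 1032 within the RNA type, and with split controls means of 971.3 and 770.3. There independent lists share 465 rises and 26.6 falls for cold and wounding, and 595.6 and 51.6 for cold and heat. Cold and heat also had 313 genes called in opposite directions within the RNA type (357.7 for independent lists), against 51 for cold and wounding (241.1 for independent lists). Against 6 controls the opposite calls were 73 for cold and heat (41.6 for independent lists) and 5 for cold and wounding (15.8).

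The active marks H3K4me3 and H3K9ac, found at the starts of transcribed genes, overlapped far more than moved peaks. The H3K4me3 library had 96221 peaks over 114.2 Mb and the H3K9ac library 139713 over 137.4 Mb. On the 7 chromosomes 77.2% of H3K4me3 peaks (95% Wilson interval 76.9 to 77.5) were touched by an H3K9ac peak, against 4.8% for H3K4me3 peaks placed at random in the chromosome and 7.2% for peaks moved by 200 to 1000 kb. In reverse 56.7% of H3K9ac peaks were touched by an H3K4me3 peak, against 3.6% and 5.4%. Intervals here and below cover counting error only, and each mark has no replicate. H3K27me3, the mark of Polycomb repression, touched 50.6% of H3K4me3 peaks and 54.9% of H3K9ac peaks, against 15.3% and 15.9% after moves of 200 to 1000 kb. H3K4me3 peaks with H3K9ac and H3K27me3 numbered 36065, with H3K9ac alone 32166, with H3K27me3 alone 8698 and with neither 11458. The median length was 1122 bp and 1120 bp in the groups with H3K9ac and 307 bp and 310 bp in those without. Without ABA, H3K27me3 was the mark most concentrated towards chromosome ends. The outer 10% at each chromosome end held 75.6% ± 11.4 of its covered bases (SD over 7 chromosomes), against 39.8% ± 5.2 for H3K4me3 and 39.2% ± 4.8 for H3K9ac. Its coverage ranged from 2.44% of chromosome 4 to 8.42% of chromosome 7, while that of H3K4me3 ranged from 1.83% to 2.51%. Its longest peak spanned 133937 bp on chromosome 1 (14386695 to 14520631), with an authors' fold enrichment of 57.5 at the summit. The build behind these coordinates is not given in the sources used here, so no gene is assigned to them.

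**Figure D4:**
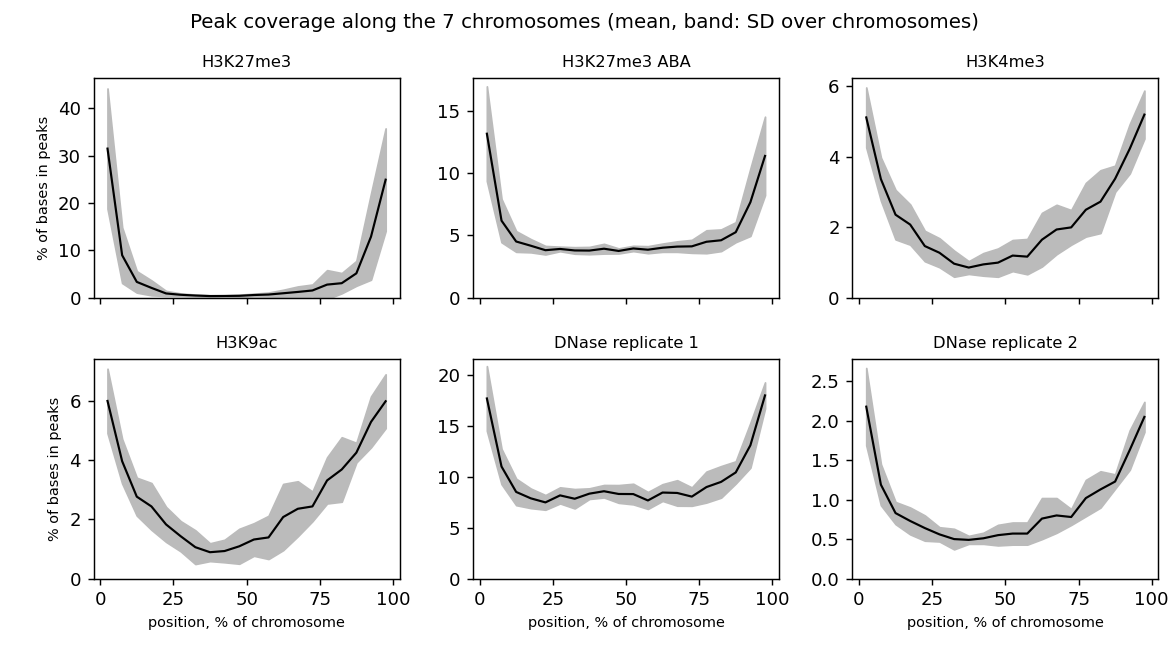
Share of bases in peaks (%) along the chromosome in 20 equal bins, as the mean (line) and SD (band) over 7 chromosomes, for each of 6 peak lists; the vertical scales differ. H3K27me3 without ABA covers 31.5% of the outermost bin at one end and 0.36% in the middle, and H3K27me3 after ABA covers 13.2% and 3.75% of the same bins.

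DNase-hypersensitive sites were more often marked in replicate 2 than in replicate 1, which had far more peaks. Of 102072 replicate 2 peaks on the chromosomes, 59.3% were touched by H3K9ac, 45.2% by H3K4me3 and 37.8% by H3K27me3, against 5.1%, 4.0% and 11.7% after moves of 200 to 1000 kb. A share of 32.5% met only active marks, 28.7% active marks and H3K27me3, 9.1% only H3K27me3 and 29.6% no mark. For replicate 1 peaks the shares were 7.4%, 7.8%, 9.9% and 75% in the same order. Both DNase alignments are named as merged, and the sources do not say of what, so the overlap of their peaks is no measure of biological agreement. The DNase replicates differed in depth 7.1 times and in peak number 8.27 times, 898829 for replicate 1 and 108693 for replicate 2. Replicate 1 touched 89.5% of replicate 2 peaks (95% Wilson interval 89.3 to 89.7; 16.8% for random placement), and replicate 2 touched 8.1% of replicate 1 peaks (2.0% for random placement). The recovered share was 99.3% for replicate 2 peaks with only active marks and 68.5% for those with no mark. Only 16.9% of replicate 2 peaks had a replicate 1 peak with reciprocal overlap of 50%.

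H3K27me3 after ABA differed from H3K27me3 without ABA in peak number, length and place, with 1 library per condition and so no replicate check. The labels give no age for the library without ABA, so plant age is not separated from ABA either. The library after ABA had 538720 peaks with a median of 340 bp and the other 156832 with a median of 531 bp, yet they covered 253.9 and 261.7 Mb. Peaks of 10 kb or longer numbered 9 after ABA and 5003 without. Peaks of the library without ABA were touched by an ABA peak in 50.3% of cases (95% Wilson interval 50.1 to 50.6), against 23.4% after moves of 200 to 1000 kb, and 26.8% of ABA peaks touched one without ABA. These shares depend on list length and on the overlap asked for: with as many top ABA peaks as the other list holds they were 33.3% and 64.9%, and with 50% of the peak covered 28.2% and 25.5%. Of the 5000 peaks with the highest fold enrichment, with a median of 8846 bp, 99.7% were touched, against 56.4% after moves, and 48.5% of their bases were covered, against 13.4%. Of the weakest 20%, with a median of 285 bp, 23% were touched, against 15.6% after moves, and 15.8% of the bases were covered, against 10.5%. Among peaks of 1 to 2 kb, 86.8% of the stronger 50% by fold and 56.5% of the weaker 50% were touched. The 133937 bp peak on chromosome 1 met 65 separate ABA peaks that covered 42.6% of it. In the middle 20% of the chromosomes 3.87% ± 0.18 of bases (SD over 7 chromosomes) lay in peaks after ABA and 0.46% ± 0.22 without. The outer 10% at each end held 36.4% ± 5.9 of the covered bases after ABA. The longest peak present only without ABA was 9020 bp on chromosome 2 (27070733 to 27079752), followed by 8761 bp on chromosome 7 (698939939 to 698948699), 8330 bp on chromosome 4 (607025734 to 607034063), 7152 bp on chromosome 1 (529043059 to 529050210) and 6721 bp on chromosome 3 (731720744 to 731727464). The longest present only after ABA were 7686 bp on chromosome 2 (687491983 to 687499668), 7392 bp on chromosome 4 (395619107 to 395626498), 7167 bp on chromosome 3 (497831250 to 497838416), 7040 bp on chromosome 3 (653113988 to 653121027) and 6859 bp on chromosome 4 (569433826 to 569440684).

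**Figure D5:**
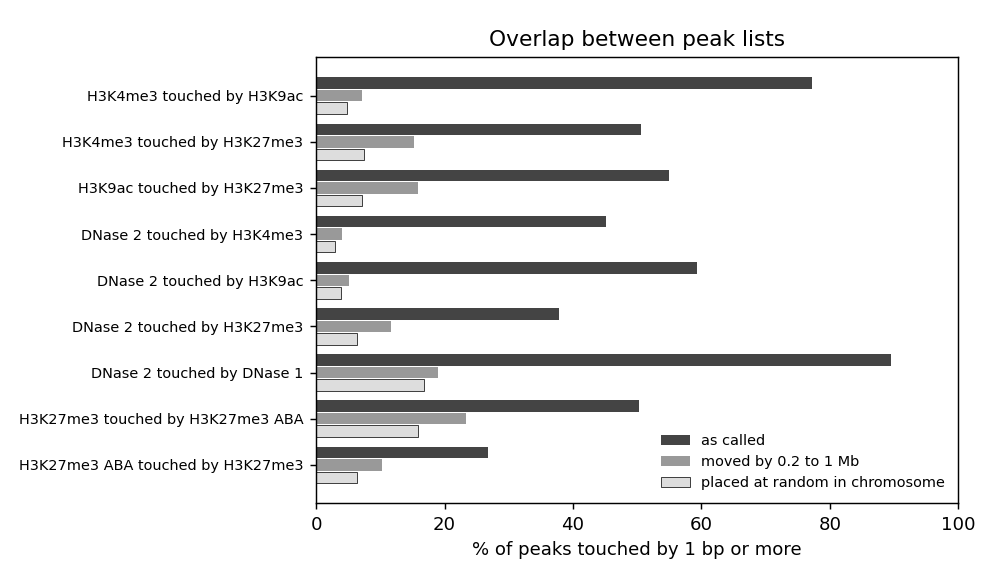
Share of peaks (%) of one list touched by at least 1 bp of another, as called, after moves of 0.2 to 1 Mb, and after random placement in the chromosome (means of 100 draws). H3K4me3 peaks are touched by H3K9ac in 77.2% of cases and in 7.2% after moves.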

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

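All flags below come from 27 tests of the 6 control libraries, a fixed rule that compares the gap of the most extreme library with the whole range. Its limit would flag about 1 in 20 groups of 6 values drawn from 1 normal distribution. These controls mix RNA types, so the rate of chance flags here is not known.

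TuG1812G0600002471.01, which rose after drought, stood at 8.77 FPKM in control replicate 3, and the gap to the next library was 0.877 of the range. Among the 6 controls, control replicate 3 also had the highest correlation across genes with each drought library, 0.950 and 0.932, against 0.927 and 0.931 at most for the others. TuG1812G0400002665.01, which rose after heat, stood at 0.356 FPKM in control replicate 4, a gap of 0.725 of the range, from 4 reads. No explanation was tested for either.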

How the results depend on the processing

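The RNA type term (poly(A) or total RNA, per the labels), its combinations, voom on recovered reads and 2 fits that kept genes below the filter were chosen after the data were seen. Counts are genes past adjusted p 0.05 in limma, and the cause of each shift was not tested unless stated. Main counts for ABA, drought, cold, heat and wounding were 5556, 44, 569, 2878 and 1141, with 0 for salt. Counts not listed lay within 1.5 times of these.

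Scaling gave the following. TMM called 1816 for ABA, 126 for drought, 1427 for cold and 2685 for wounding. Quantile normalization called 1804 for ABA, 94 for drought, 1273 for cold and 2745 for wounding. Voom on recovered reads called 2233 for ABA, 1165 for cold, 4382 for heat and 2573 for wounding. For ABA a pseudocount of 0.1 gave 3478, and a filter at 5 FPKM, which tests fewer genes, gave 3382.

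Control replicates 1 and 2 are poly(A) RNA and the others total RNA, so these choices change the RNA type compared. With only control replicates 1 and 2 the calls were 3031 for ABA, 9698 for salt, 10128 for drought, 9863 for cold, 10258 for heat and 9010 for wounding. With only replicates 3 and 4 they were 12904 for ABA, 1 for salt, 74 for drought, 1929 for cold, 6470 for heat and 4819 for wounding. With only replicates 5 and 6 they were 12187, 18, 1131, 2296, 5297 and 3876 in the same order. Fits with only the 2 groups compared, which have fewer libraries, called 1091 for ABA, 0 for drought (salt also stayed at 0), 115 for cold, 915 for heat and 330 for wounding.

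The RNA type term called 2578 for ABA, 557 for drought, 2616 for cold, 7033 for heat and 5128 for wounding. With TMM added these were 1960, 678, 3396, 5308 and 4789, and with voom added 3054, 551, 3074, 5304 and 4620. With control replicate 3 left out as well the RNA type term called 3498 for ABA, 2 for salt, 1523 for drought, 3236 for cold, 6612 for heat and 5018 for wounding.

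Leaving out 1 library at a time gave 301 to 9819 calls for ABA, 0 to 0 for salt, 3 to 245 for drought, 80 to 900 for cold, 631 to 3199 for heat and 242 to 1482 for wounding. Where a stress kept 1 library, that library is assumed to vary like the other groups.

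Replicate numbers are shared by all groups, but the correlations of replicate 1 and 2 deviations over 21 pairs of groups ran from -0.11 to 0.29, with 10 above 0.1, so the numbers were not taken as pairing. Of 14 libraries, 14 were closest to their own number, a hint from the data only. In this measure the 2 replicates of a group mirror each other, so each group gives only 1 outcome. With the replicate block the calls were 3256 for ABA, 9914 for salt, 10272 for drought, 10076 for cold, 10422 for heat and 9212 for wounding; by its construction this fit compares each stress with control replicates 1 and 2, which are of another RNA type than all stresses but ABA.

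Over 510 fits of the 20 named results 435 kept the call and 75 lost it. No direction reversed, but the naming rule put both stress libraries outside the range of all controls. Fits that only drop libraries, change the controls compared, or change the pseudocount or filter therefore could not reverse a direction. Only fits with TMM, quantile scaling or voom could have done so. For 10 of the 20 the call held in each fit that tested them. Voom did not test 5 of the 20, 2 of these 10 among them (TuG1812G0400002666.01 and TuG1812G0300004779.01), as their reads were not all recovered. TuG1812G0400002666.01 and TuG1812G0400002665.01 fell below the filter without either heat library. In fits that kept the 18308 genes their log2 changes were 11.95 and 9.56 without heat replicate 1 and 10.92 and 8.35 without replicate 2, with adjusted p of 8.53e-11 or less. The ABA falls of TuG1812G0200002505.01 and TuG1812S0000304700.01 each lost the call in 16 fits.

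Shared calls with the RNA type term were 2966 for heat and wounding, 1291 for cold and wounding and 1032 for cold and heat. The H3K27me3 share of peaks touched after ABA was 65.8% in the better part of each list by q, 33.3% with as many top ABA peaks as the other list holds and 28.2% when 50% of the peak must be covered. In reverse it was 40.1%, 64.9% and 25.5%. The DNase share was 73.0% with equal numbers of peaks and 16.9% with reciprocal overlap. Gene lists, marks at genes and the ABA change of H3K27me3 against RNA were not run, for lack of names and gene coordinates. For simulated heat versus control, the model with 6 controls found 1% of genes changed by 1 on the log2 scale. The model with the RNA type found 38% on the same libraries, 2 per stress. Small changes are therefore below the reach of the first model and often missed by the second.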

Other observations

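Of the tests below, those on RNA type, tag numbers, chromatin enrichment and 2 more weeks of plant age were chosen only after the result was seen.

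Within the RNA types, ABA and cold moved more genes in opposite directions than alike. There, where they share no control, 372 genes were called in opposite directions and 149 in the same direction, while independent lists would give 154.5 opposite, 181.8 rising together and 32 falling together. Of the 372, 313 were lower after ABA and higher after cold, and 59 the reverse. With TMM scaling 407 were opposite and 125 alike, against 183.7 and 179.9 for independent lists. Against 6 controls this excess was absent, with 67 opposite (70.5 for independent lists), 78 rising together (101.4) and 3 falling together (0.8). ABA and heat leaned the other way within the RNA types, with 719 alike and 204 opposite, against 535 rising together, 63.4 falling together and 391.9 opposite for independent lists; against 6 controls 738 rose together (591.3), 29 fell together (3.3) and 92 were opposite (278.8). ABA was measured in poly(A) RNA and cold in total RNA, and the treatments lasted 2 weeks and 5 h.

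A small group of genes was called in the same direction after heat, wounding, cold and drought. Within total RNA 73 genes rose and 38 fell in all 4, against 3.22 and 0.02 for independent lists, and with TMM scaling 59 rose and 93 fell, against 0.68 and 0.51. These stresses share control replicates 3 to 6, and how much of the excess comes through those controls was not measured. Many of the most abundant genes fell after heat, wounding, cold and drought. Of the 100 genes with the highest mean FPKM, 59 fell and 8 rose after heat, 50 fell and 7 rose after wounding, 32 fell and 2 rose after cold and 21 fell and 1 rose after drought, within total RNA. Of all tested genes 7.5%, 3.9%, 3.8% and 0.8% fell in these stresses. The 100 were ranked on the same libraries that were tested, where controls outnumber each stress, so the ranking favours genes high in controls. What part of the excess of falls comes from this choice was not measured. With TMM scaling 67, 60, 29 and 15 of the 100 fell, and 2756, 2216, 1514 and 341 of all 18308 tested genes. After ABA, within poly(A) RNA, 3 of the 100 fell and 5 rose, and after salt 0 were called. These 100 genes held 46.7% to 57.8% of the FPKM sum in control replicates 3 to 6 and 26.4% to 34% after heat.

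The RNA types differ gene by gene. In all 14 total RNA libraries 15 genes were at 100 FPKM or more that were under 10 FPKM in all 4 poly(A) libraries, and 1 gene showed the reverse. At limits of 10 and 1 FPKM the numbers were 47 and 8.

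A first pattern is the distance of control replicates 1 and 2 and the ABA libraries from the other 14. A single scale factor per library would remove it, but 7676 genes passed after TMM scaling; 7600 passed after the 100 most abundant genes were left out, and 7231 after thinning to 2534878 reads, so abundant genes and depth are not the whole cause. Drought plants, also 2 weeks older, correlated at most 0.791 with the 4 libraries and at least 0.822 with the others. This argues only against that age as the sole cause. The drought libraries are total RNA, so the comparison cannot say whether age adds to a difference by RNA type. RNA type is a candidate explanation: the label, poly(A) or total RNA, matched the side of the largest gap on the main axis for 18 of 18 libraries, and the FPKM sums did not overlap (573184 or more against 347068 or less). Age or growth of the control plants cannot be told apart from it, since 0 control libraries have an age in their labels and only the control group has both RNA types.

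A second pattern is that H3K27me3 peaks after ABA were more numerous and shorter, with 1 library per condition. More reads are excluded, as the ABA library had 0.95 times the tags. Lower enrichment in the ABA library stays open. Peaks found only after ABA had 12.1% of their bases in the outer 10% at each chromosome end, while peaks placed at random that touched no peak of the other library had 15.8% (15.7% to 16.0% over 100 placements). The share is therefore near that of scattered background but outside its range, and a real gain away from the ends would lower it too. Redistribution by ABA cannot be told apart from lower enrichment with 1 library per condition.

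The last pattern is the excess of rises after heat and wounding within total RNA. With TMM scaling rises were 48.1% of calls for heat and 53.7% for wounding, which is the outcome expected if falling abundant genes lifted the rest. The test does not decide, because TMM itself centres all genes at a median within 0.01 of 0. Whether transcripts rose per cell or only relative to the abundant genes stays open, and so does a biological excess of rises.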
